A study of Mus musculus with 12 samples.

How the data were processed

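The series holds 12 libraries of cultured mouse colon fibroblasts in 3 groups of 4. Per the labels' protocols, C57BL/6 cells from mice 12 weeks old were grown in medium with 10% fetal bovine serum and harvested 24 h after plating at about 80% confluency, with no treatment. Libraries were made from 200 ng of total RNA with a kit that sequences the 3' ends of messenger RNA (QuantSeq, forward version) and read from 1 end to 75 nt on a NextSeq 500. The labels call unique molecular identifiers optional. Whether they were used or counted, the aligner, the counting tool and the gene annotation are not given in the sources used here, and nor is whether the counting used the strand. The genome build was GRCm38, per the submitters' processing notes.

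The authors deposited 1 table of a depth-normalised signal per gene and library, in which every column sums to 10000000. A value is thus the number of reads of a gene per 10000000 reads assigned to genes, called normalised reads here. The low values of each column were whole multiples of 1 step, and dividing by that step gave whole reads, within a tolerance of 0.01 read, for 100% of values. The largest deviation was 3.965e-05 read. The recovered depth was 2.67 to 5.20 M reads per library, so 1 read was worth 1.92 to 3.75 units and 3 reads 5.77 to 11.2 units. The table held 23106 genes, of which 23002 were matched by identifier to a symbol in the GENCODE vM21 annotation of GRCm38, the source of all coordinates, and 104 were not. All columns were matched to samples by name.

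Genes with a mean of at least 10 normalised reads over the 12 libraries were tested, which left 12676. The values were taken to log2 after adding 1, so a log2 change is on the log2(value + 1) scale and understates the change of low genes. Group means of all 12 libraries were fitted in 1 model with limma 3.58.1 (trend option, R 4.3.3), the 3 differences between groups were tested, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The genes Sox2, Igtp, Eng, Hoxc5, Hoxc6, Hoxc8, Hoxc9 and Hoxc10 overlap other tested genes on the same strand. Cyp51, Aldh1l2, Ogn, Tmem176a, Tmem176b, Igf2r, Ddit3, Col5a1, Sfrp2, Synm, Asb5, Hand2, Hoxa11, Atf5, Rbms3, Amigo2, Pusl1, Cbx7, Mab21l1, Mab21l2, Nnat and Ccnd1 overlap a tested gene on the other strand. Their values are uncertain as far as the counting could split or share reads, and so are those of ribosomal protein genes, which have many pseudogene copies, and of Ly6c1 and Trbc2, which have near-identical copies.

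The 42 gene lists comprised 32 of pathways and cell states, 8 of markers of other cell types and 2 of RNA quality. The 34 lists with at least 5 tested members entered limma's camera test with a preset correlation of 0.01, adjusted over the lists, beside camera with an estimated correlation and fry. Lists said to be called passed camera with the preset correlation. The fry test also passed lists that this camera test did not. Examples are matrix proteases in Prkcz-/- against WT (fry adjusted p = 1.8e-06) and myofibroblastic markers in the Sox2 guide against WT (fry adjusted p = 1.6e-05). Setting genes with 0 reads in a group to their bound left the medians of called lists as printed. The 4 genes of the design and title (Prkcz, Sox2, Sfrp1 and Sfrp2) also had an exact two-sided permutation test of the difference of mean log2 values, over the 70 assignments of 8 libraries, whose smallest possible p is 0.0286. Replicates were checked against each other by a chi-square test of reads over genes.

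Groups, tests, gene lists, the rule for naming genes and nearly all alternatives were chosen before the data were examined. The rule took the 4 design and title genes, the 8 largest increases and 8 largest decreases per comparison among called genes whose groups did not overlap and whose mean was at least 50 normalised reads (predicted genes, Rik clones and ribosomal pseudogenes left out), up to 4 called members of each list (the 2 smallest adjusted p in each direction), and 8 genes in each direction for the reversal. Some results under this rule are not reported here. Genes named outside it were chosen after their values were seen, and are said to be. In the comparison of reversal, unchanged groups were simulated around the shared libraries, the overlap of independent lists was computed, and the shared libraries were split between the contrasts.

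The limma fit and the camera test were tried on simulated reads with known changes. For limma, only 67, 67 and 66 genes were changed 1.5-fold, 2-fold and 4-fold in each comparison. Far more genes passed in the data, so the shares of false calls below do not carry over to them. In the comparison labelled Prkcz-/- against WT, over 12566 genes, 52.2% of genes changed 1.5-fold, 95.5% changed 2-fold and 100% changed 4-fold were recovered, and 0.0728% of unchanged genes were called. For the Sox2 guide against Prkcz-/- these shares were 70.1%, 91.0% and 100% over 12570 genes, with 0.0485% false calls. For the Sox2 guide against WT they were 67.2%, 94.0% and 100% over 12562 genes, with 0.0566% false calls.

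The alternatives were other pseudocounts (0.5 and 5), no filter and a filter at 50 normalised reads, median-of-ratios and quantile scaling, a robust prior, array weights, the replicate number as a block, a fit of only the libraries compared, a 1.5-fold threshold, leaving out each library in turn, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads. On those reads edgeR called 8550, 8055 and 6647 genes in the 3 comparisons. A scaling to the reads outside mitochondrial genes and Gm42418 was added after seeing the data. Equal column totals, also listed, changed nothing since the totals already were equal. Intervals and floors of 3 reads cover counting error only. Plots were drawn with matplotlib 3.10.9.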

Results

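Transcript levels were measured in cultured fibroblasts of the mouse colon by 3' tag sequencing, in which a read marks the 3' end of a messenger RNA. The 12 libraries formed 3 groups of 4 replicates: cells labelled wild type with a guide named sgScr (WT-labelled), cells labelled Prkcz-/- with sgScr (knockout-labelled), and cells labelled Prkcz-/- with a guide against Sox2 (Sox2-guide libraries). Prkcz encodes protein kinase C zeta, an atypical protein kinase C, and Sox2 a transcription factor of pluripotent and neural stem cells. The design asks what differs with the loss of Prkcz, and which of those differences are lower or absent when Sox2 is targeted as well. The series calls the replicates biological but does not say whether they were separate animals or cultures, so p-values measure the spread between these libraries.

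Libraries held 2.67 to 5.20 M reads, 43.3 M in all, and 14906 to 16639 detected genes. Mean depth was 3.06 ± 0.234 M reads (SD, n = 4) in the WT-labelled, 3.66 ± 0.852 in the knockout-labelled and 4.10 ± 1.07 in the Sox2-guide group. The groups separated on the first 2 principal components, which held 56.8% and 26.9% of the variance. Replicates correlated at 0.96 to 0.98 on the log2 scale across genes, and every pair differed by more than read sampling alone gives. Noise of library preparation would also do that, so the test does not rule out a repeat, and all 12 libraries were kept as separate. The biological coefficient of variation was 4.35%, 7.94% and 16.5% in the same order of groups, the last 9.51% without Sox2-guide replicate 1. Pairs with that library had a chi-square of 29.5 to 33.3 per degree of freedom, and the other pairs of its group 2.51 to 5.65. Reads of mitochondrial genes made up 10.6 ± 0.0869%, 11.2 ± 0.520% and 8.41 ± 2.77%, the last including replicate 1 at 4.29%. Malat1, a nuclear noncoding RNA, took 0.472 ± 0.0542%, 1.42 ± 0.0602% and 0.505 ± 0.127% of reads (SD, n = 4).

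The targeted genes were examined first, since they check the labels. Prkcz (ENSMUSG00000029053, chromosome 4, 155260129 to 155361361, GRCm38) had 0 reads in all 4 WT-labelled libraries, 21.3 ± 8.03 normalised reads (scaled to 10000000 per library) in the knockout-labelled (32 reads, n = 4) and 34.8 ± 11.8 in the Sox2-guide libraries (54 reads, n = 4). Its level was at least 8.92-fold and at least 13.4-fold higher than in the WT-labelled libraries, against a floor of 3 reads over the group. Taken alone, this would go against the labels, but it does not settle them, so groups are named by their labels throughout. A 3' tag outside the deleted part of Prkcz checks nothing, and the deleted part is not given in the sources used here. Between the Sox2-guide and knockout-labelled libraries the log2 change of Prkcz was 0.74 (limma adjusted p = 0.16).

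Sox2 (ENSMUSG00000074637, chromosome 3, 34650405 to 34652461) rose from 1.72 ± 1.995 normalised reads (2 reads) in WT-labelled to 1347 ± 76.4 (1960 reads) in knockout-labelled libraries, a ratio of reads of 819 (226 to 6769.5) with its 95% counting interval. It had 0 reads in the Sox2-guide libraries, at least 733-fold fewer than in the knockout-labelled. The WT-labelled libraries were near 0 without that guide, so 0 reads do not by themselves show that the guide acted. Sfrp1 (ENSMUSG00000031548, chromosome 8, 23411502 to 23449632), a secreted antagonist of Wnt ligands, rose from 16.97 ± 8.93 to 15718 ± 365 and was at 69.9 ± 12.04 in Sox2-guide libraries. Its relative Sfrp2 (ENSMUSG00000027996, chromosome 3, 83766321 to 83774316) went from 35.6 ± 10.996 to 272 ± 26.1 and 76.8 ± 14.9 (SD, n = 4 for each). Both Sfrp genes are in the series title, which was written with these samples in hand, so they are not independent evidence. In exact two-sided permutation tests, 11 of the 12 differences among the 4 genes and 3 pairs of groups had p = 0.0286 (adjusted p = 0.0312), the smallest the test can give. Sox2 between the Sox2-guide and WT-labelled libraries had an exact p of 0.43. The limma test called the same differences except Prkcz between the Sox2-guide and knockout-labelled libraries.

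**Figure D1:**
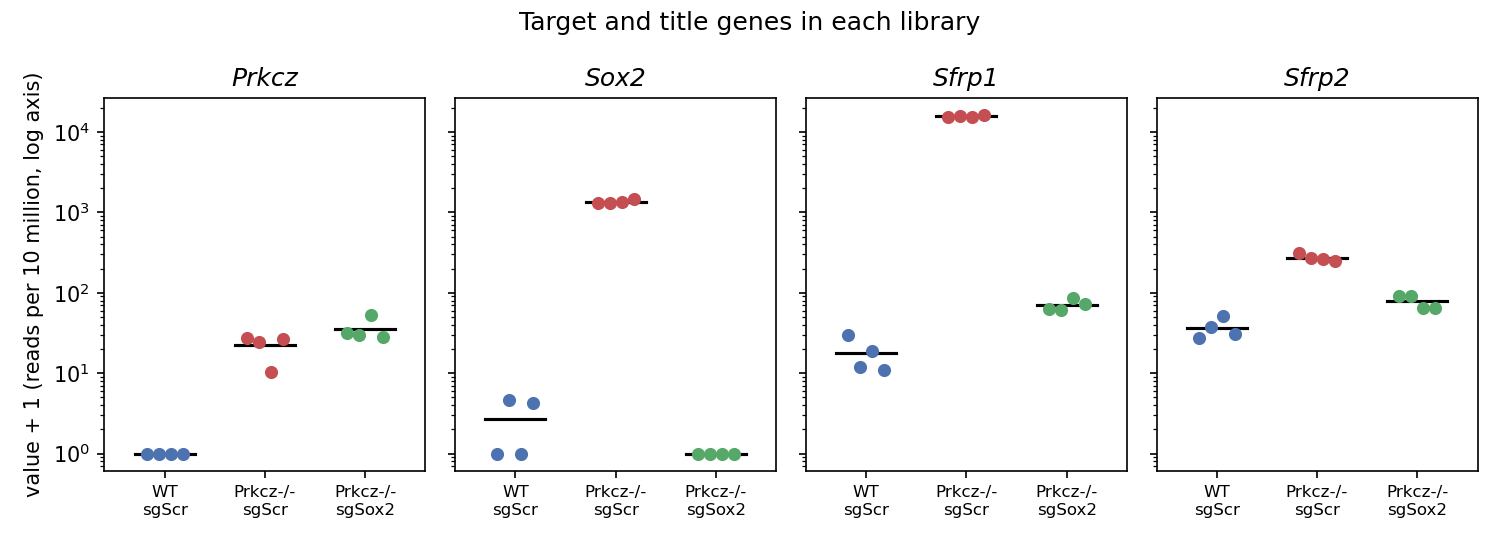
Values of Prkcz, Sox2, Sfrp1 and Sfrp2 in each of the 12 libraries, as normalised reads plus 1 on a log axis, with a bar at the mean of each group of 4. Prkcz sits at 0 reads in the WT-labelled libraries, and Sox2 and Sfrp1 are highest in the knockout-labelled ones.

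To find what differed with the Prkcz label, knockout-labelled libraries were compared with WT-labelled ones. Rspo2, a secreted enhancer of Wnt signalling, rose from 4.99 ± 4.19 to 3127 ± 173 normalised reads, and Hoxc8, Hoxc9 and Hoxc10 from 0, 3 and 0 reads to 1061 ± 73.8, 1729.7 ± 78.5 and 639 ± 89.6. Fbln7, a matrix protein, rose from 1 read to 1174 ± 99.9, and Bend5 from 0 reads to 573 ± 50.3, at least 237-fold. Pitx1, a transcription factor of hindlimb development, fell from 1057 ± 109.7 to 0.508 ± 1.02, Nkx2-3, a homeobox factor of gut mesenchyme, from 712 ± 53.8 to 1.29 ± 1.56, and Hoxd13 from 583 ± 53.4 to 1.02 ± 2.03. Also lower were Dpt (1153 ± 40.5 to 1.62 ± 3.24), a matrix protein of fibroblasts, and Msln (1111 ± 56.2 to 0.782 ± 1.56), a marker of mesothelium. So were Asb5 (1588 ± 138 to 3.87 ± 4.67), Brinp1 (632 ± 81.03 to 0) and Spock3 (497 ± 84.7 to 0.508 ± 1.02). The SD of each is over n = 4 libraries.

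In all, 8493 of 12676 tested genes (67.0%) passed limma at an adjusted p under 0.05, 4760 higher and 3733 lower in the knockout-labelled libraries. Of these, 2629 were at least 2-fold higher and 1668 at least 2-fold lower, and 594 and 290 at least 8-fold. The values of 8366 genes (66.0%) did not overlap between the groups, where chance gives 2.86%. The root mean square log2 difference between the group means was 1.62, against 0.42 and 0.37 between replicates. Quantile scaling moved the median log2 change of all tested genes by -0.17 and turned the split to 4088 higher and 4447 lower (47.9% higher against 56.0%).

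Lists of myofibroblastic markers, matrix proteins and TGF-beta and BMP genes were higher, none of them called with an estimated correlation. Of the markers of myofibroblastic cancer-associated fibroblasts, 13 rose and 2 fell of 18 tested (median log2 change 1.88, adjusted p = 0.0014, and adjusted p = 0.085 with an estimated correlation). Postn, periostin, rose from 227 ± 45.7 to 14452 ± 1145 normalised reads and Acta2, smooth muscle actin, from 1609 ± 61.9 to 25553 ± 1214, while Thy1 (942 ± 88.9 to 146 ± 7.06) and Inhba (488 ± 30.6 to 91.2 ± 7.04) fell. Among collagens, 15 rose and 2 fell of 18 (median log2 change 1.58, adjusted p = 3.2e-04, and adjusted p = 0.19 with an estimated correlation), with Col1a1 from 5829 ± 297 to 57381 ± 2859.6 and Col5a1 from 484 ± 32.6 to 4432 ± 202. Of the noncollagenous matrix proteins 19 rose and 3 fell of 25 (median log2 change 1.14, adjusted p = 0.0011, and adjusted p = 0.076 with an estimated correlation): Ogn rose to 2885 ± 218 from 171 ± 30.8, and Dcn, decorin, fell from 1374 ± 93.8 to 55.3 ± 20.4. Matrix proteases, inhibitors and crosslinkers went both ways and were not called (15 rose and 10 fell of 27; median log2 change 1.22, adjusted p = 0.38, and adjusted p = 0.65 with an estimated correlation). Camera with edgeR called them (median log2 change 1.16, adjusted p = 0.033). TGF-beta response genes (14 rose and 2 fell of 22; median log2 change 0.75, adjusted p = 0.0083, and adjusted p = 0.26 with an estimated correlation) included Tgfbi (56.7 ± 19.2 to 2026 ± 122) and Tgfb2 (103 ± 7.85 to 1629.7 ± 135). Of the BMP ligands, antagonists and targets 12 rose and 3 fell of 16 (median log2 change 1.33, adjusted p = 0.012, and adjusted p = 0.16 with an estimated correlation), with Id3 and Fstl1 higher by log2 2.03 ± 0.10 and 1.80 ± 0.08 (SE). Nog, noggin, changed by -2.84 ± 0.24. Smooth muscle markers, a sign of another cell type, were not called as a list (median log2 change 1.73, adjusted p = 0.59), though Lmod1 rose from 8.03 ± 6.31 to 654 ± 23.4. Camera with edgeR on the recovered reads did call them higher (median log2 change 1.63, adjusted p = 0.029). Of pericyte markers, also of another cell type and too few for the list test, 2 rose and 1 fell of 4 (median log2 change 1.40).

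Mitosis and ribosomal protein genes fell. All 31 mitosis genes were lower (median log2 change -1.26, adjusted p = 1.3e-13, and adjusted p = 0.0011 with an estimated correlation), among them Kif23 (2977 ± 25.6 to 434 ± 42.7) and Ccnb1, cyclin B1 (2151 ± 98.7 to 582 ± 75.96). DNA replication and S phase genes were not called as a list (7 rose and 13 fell of 29; median log2 change -0.22, adjusted p = 0.12, and adjusted p = 0.38 with an estimated correlation). Of 44 cytosolic ribosomal protein genes, a list set for RNA quality, 43 were lower and 0 higher (median log2 change -0.90, adjusted p = 2.5e-13, and adjusted p = 0.19 with an estimated correlation), with Rpl4 from 15113 ± 374 to 5620.1 ± 296. In these libraries Malat1 took 1.42% of reads against 0.472% in the WT-labelled. Glycolysis and hypoxia genes (5 rose and 20 fell of 28; median log2 change -1.05, adjusted p = 6.3e-04, and adjusted p = 0.16 with an estimated correlation) included lower Ldha, lactate dehydrogenase, and Eno1 (log2 -2.03 ± 0.10 and -2.22 ± 0.13), and a higher Adm (2.94 ± 0.21). Cholesterol synthesis genes (1 rose and 13 fell of 22; median log2 change -0.43, adjusted p = 0.0031, and adjusted p = 0.16 with an estimated correlation), AP-1 and immediate early genes (3 rose and 15 fell of 25; median log2 change -0.86, adjusted p = 7.1e-04, and adjusted p = 0.16 with an estimated correlation) and Wnt/beta-catenin targets (0 rose and 6 fell of 8; median log2 change -1.30, adjusted p = 0.016, and adjusted p = 0.25 with an estimated correlation) were lower as lists. The Wnt target call ended with no filter on low values. The log2 change was -1.69 ± 0.08 for Msmo1, an enzyme of sterol synthesis, and -3.47 ± 0.12 and -4.64 ± 0.21 for Spry2 and Dusp4, brakes on MAP kinase signalling. Ccnd1, cyclin D1, fell from 6171 ± 282 to 329 ± 34.1. Of mesothelial markers, of another cell type, 0 rose and 2 fell of 2, Krt19 among them being an epithelial marker as well (median log2 change -7.10), and of those of interstitial cells of Cajal 1 rose and 2 fell of 3 (-3.57). Of epithelial markers 1 rose and 2 fell of 3 (-4.37), of immune cell markers 1 rose and 1 fell of 2 (0.90) and of enteric glia and neuron markers 2 rose and 1 fell of 4 (0.06), all too few for the list test. Endothelial markers were not called (2 rose and 1 fell of 5; median log2 change 0.51, adjusted p = 0.86, and adjusted p = 0.89 with an estimated correlation).

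Interferon-stimulated genes had the largest median among the 15 called lists. Of 34, 33 rose and 1 fell (median log2 change 3.37, adjusted p = 6.6e-16, and adjusted p = 0.069 with an estimated correlation). Gbp3 rose from 109 ± 16.3 to 1911 ± 145 and Igtp from 173 ± 9.71 to 2909 ± 167, both interferon-inducible GTPases, and the exception was Oasl1 (158 ± 16.5 to 19.6 ± 7.203). Of p53 target genes 13 rose and 3 fell of 20 (median log2 change 1.53, adjusted p = 0.002, and adjusted p = 0.098 with an estimated correlation), with Trp53inp1 and Phlda3 higher by log2 4.07 ± 0.16 and 3.41 ± 0.14. Serine, one-carbon and ATF4 response genes (17 rose and 5 fell of 25; median log2 change 1.04, adjusted p = 0.0031, and adjusted p = 0.19 with an estimated correlation) included Ddit3 (3.39 ± 0.12) and Atf5 (2.58 ± 0.09), both higher, and Phgdh (-1.06 ± 0.23), lower. In these 15 called lists, counts adjusted over the list alone equalled those over all genes. With an estimated correlation only the mitosis list remained called.

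HOX genes, which set position along the body, were called as a list (17 rose and 3 fell of 28; median log2 change 0.72, adjusted p = 0.018, and adjusted p = 0.19 with an estimated correlation), a call that ended with a filter at 50 normalised reads. In the Hoxc cluster on chromosome 15, Hoxc6 rose from 25.01 ± 7.38 to 2403 ± 123, and Hoxc4, Hoxc5, Hoxc11 and Hoxc13, with 0 reads in WT-labelled libraries, stood at 124 ± 13.7, 103 ± 30.2, 84.7 ± 16.2 and 405 ± 48.3. Hoxc4, Hoxc5, Hoxc11 and Hoxc13 were singled out after their values were seen. The annotated span of Hoxc5 covers Hoxc6, Hoxc8 and Hoxc9 and part of Hoxc10 on the same strand, so all these values are uncertain. Hoxa11 fell (log2 change -2.21 ± 0.13), as did Hoxd13.

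**Figure D2:**
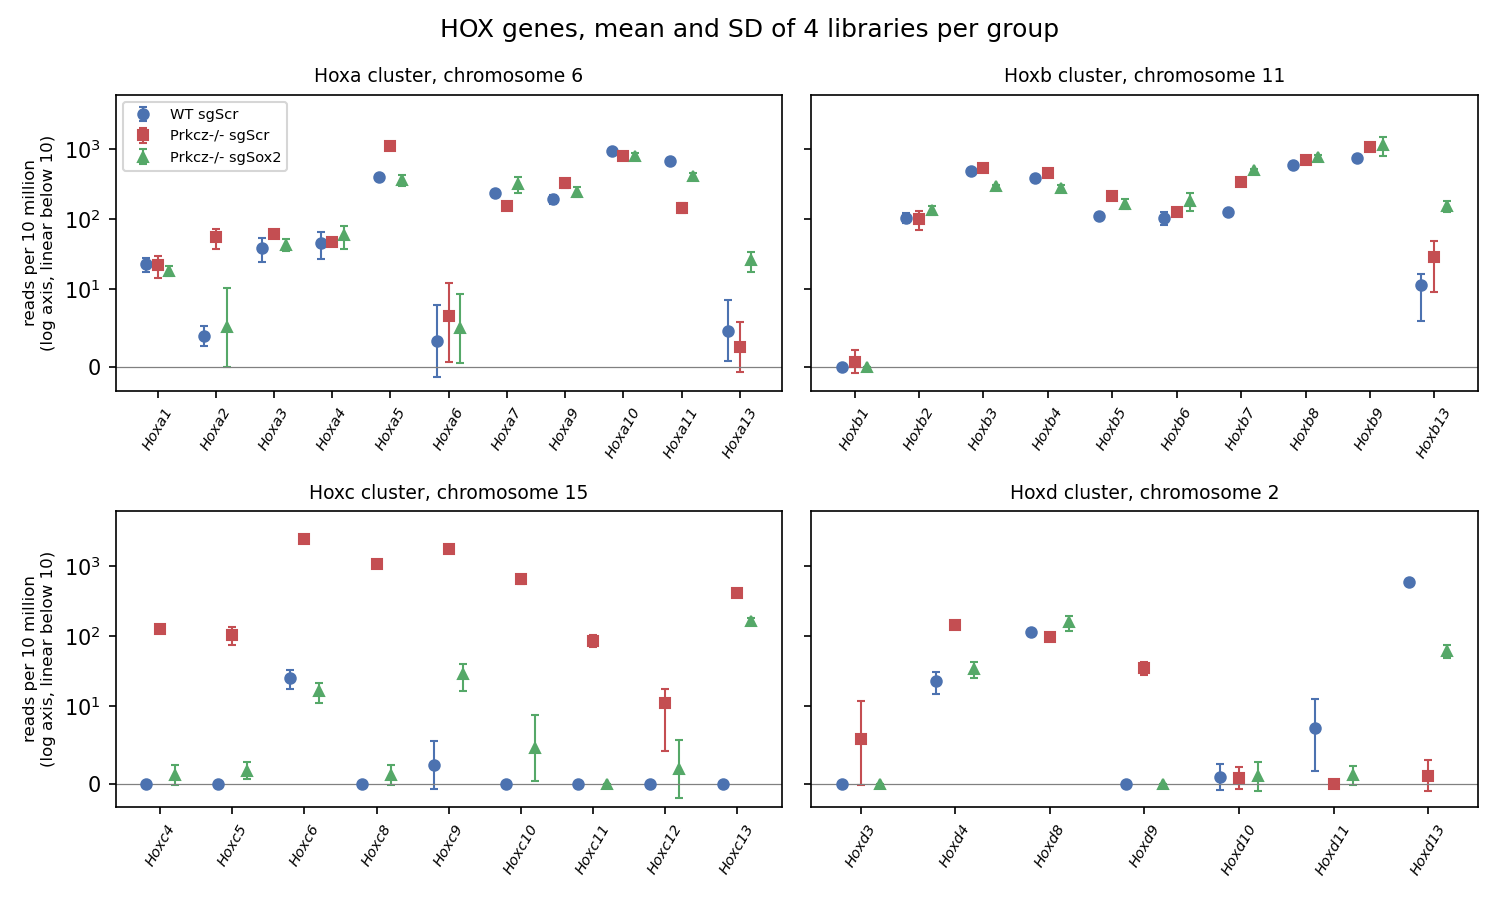
Mean and SD of 4 libraries per group for each HOX gene, as normalised reads (per 10000000) on an axis that is logarithmic above 10 and linear below. Hoxc6 stands at 25.01, 2403 and 16.04 in the WT-labelled, knockout-labelled and Sox2-guide groups, and Hoxd13 at 583, 1.02 and 61.1.

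To ask what differed with the Sox2 guide among cells labelled Prkcz-/-, Sox2-guide libraries were compared with knockout-labelled ones. Pitx1 rose from 0.508 ± 1.02 to 1212 ± 184 normalised reads and Nkx2-3 from 1.29 ± 1.56 to 1622 ± 241. Sprr1a, a cornified envelope protein, rose from 6.97 ± 1.83 to 3177 ± 479 and Pcdh17, a protocadherin, from 6.76 ± 5.39 to 1916 ± 266. Ly6c1 rose from 10.8 ± 4.02 to 1919.95 ± 331, Asb5 from 3.87 ± 4.67 to 921 ± 162, Msln from 0.782 ± 1.56 to 358 ± 84.6 and Lor, loricrin, from 0.508 ± 1.02 to 151 ± 21.3. Igsf10 fell from 1956 ± 163 to 0.556 ± 1.11 and Dkk3, a secreted protein of the dickkopf family, from 2969 ± 141 to 3.604 ± 3.17. Kctd15 fell from 1524 ± 178 to 3.67 ± 4.42 and Lama4, a laminin chain, from 828 ± 18.2 to 1.42 ± 1.798. Limch1 (1266 ± 82.1) and Cdh13 (696 ± 57.6), a cadherin, had 0 reads with the guide, at least 696-fold and 384-fold lower (SD over n = 4).

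By limma 7689 genes (60.7%) passed, 3866 higher and 3823 lower in the Sox2-guide libraries, of which 1404 and 1992 by at least 2-fold and 176 and 511 by at least 8-fold. The values of 6794 genes (53.6%) did not overlap, against 2.86% by chance. The split turned with the scaling: 4271 higher and 3445 lower by quantile scaling (55.4% higher against 50.3%), and 3632 and 4110 (46.9%) without mitochondrial genes and Gm42418, chosen after the data were seen. Without Sox2-guide replicate 1, which stood apart from the other 3, 7816 passed. The root mean square log2 difference was 1.45, with 0.47 between Sox2-guide replicates.

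Lists of myofibroblastic markers, matrix proteins, BMP and TGF-beta genes fell. Of 18 tested myofibroblastic markers 0 rose and 14 fell (median log2 change -3.02, adjusted p = 1.3e-07, and adjusted p = 0.0071 with an estimated correlation): Postn from 14452 ± 1145 to 434 ± 45.3 and Acta2 from 25553 ± 1214 to 1339.98 ± 329. Of the noncollagenous matrix proteins 2 rose and 22 fell of 25 (median log2 change -1.32, adjusted p = 1.6e-07, and adjusted p = 0.0071 with an estimated correlation), with Ogn from 2885 ± 218 to 31.9 ± 7.28 and Fn1, fibronectin, from 42618 ± 1032 to 10185 ± 1236. Among collagens 1 rose and 15 fell of 18 (median log2 change -1.45, adjusted p = 1.6e-07, and adjusted p = 0.076 with an estimated correlation), with Col6a2 from 2516 ± 176 to 122 ± 25.2 and Col11a1 from 849 ± 48.3 to 1.65 ± 1.13. BMP genes (3 rose and 11 fell of 16; median log2 change -2.25, adjusted p = 3.7e-04, and adjusted p = 0.034 with an estimated correlation) included Id2 (-2.53 ± 0.08) and Fstl1 (-2.49 ± 0.08) in log2 units, and Nog rose by 3.27 ± 0.24. Matrix proteases, inhibitors and crosslinkers were not called (9 rose and 15 fell of 27; median log2 change -0.43, adjusted p = 0.13, and adjusted p = 0.46 with an estimated correlation). Camera with edgeR called them (median log2 change -0.50, adjusted p = 0.028). TGF-beta response genes (4 rose and 13 fell of 22; median log2 change -0.75, adjusted p = 0.0011, and adjusted p = 0.17 with an estimated correlation) included Ltbp2 (-6.94 ± 0.19) and Pmepa1 (-1.95 ± 0.07). Smooth muscle markers, of another cell type, fell with them (1 rose and 5 fell of 6; median log2 change -3.63, adjusted p = 0.016, and adjusted p = 0.084 with an estimated correlation), as Lmod1 (654 ± 23.4 to 1.11 ± 2.23) and Synm (287 ± 17.6 to 13.6 ± 4.08) show. Of pericyte markers 0 rose and 3 fell of 4 tested (median log2 change -2.07).

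Lists of mitosis, S phase, ribosomal protein, cholesterol synthesis and glycolysis genes rose. All 31 mitosis genes were higher (median log2 change 1.25, adjusted p = 1.8e-13, and adjusted p = 0.0011 with an estimated correlation), with Birc5, survivin, from 2207 ± 189 to 6898 ± 653. Of 44 ribosomal protein genes 43 rose (median log2 change 1.05, adjusted p = 1.8e-15, and adjusted p = 0.14 with an estimated correlation), Rps24 by log2 1.72 ± 0.12, while Malat1 took 0.505% of reads against 1.42%. S phase genes (18 rose and 3 fell of 29; median log2 change 0.42, adjusted p = 0.0031, and adjusted p = 0.11 with an estimated correlation) included Rrm2 (1.87 ± 0.10) and Tyms (0.96 ± 0.08). Cholesterol synthesis genes (19 rose and 1 fell of 22; median log2 change 1.56, adjusted p = 3.9e-09, and adjusted p = 0.013 with an estimated correlation) included Msmo1 (489.7 ± 10.4 to 2284 ± 172) and Cyp51 (859.6 ± 39.4 to 2894 ± 115). Glycolysis and hypoxia genes (15 rose and 6 fell of 28; median log2 change 0.74, adjusted p = 0.016, and adjusted p = 0.23 with an estimated correlation) included higher Ldha and Aldoa (1.70 ± 0.10 and 1.56 ± 0.11), while Adm fell (-6.67 ± 0.21). The glycolysis call ended with a filter at 50 normalised reads. Of mesothelial markers 2 rose and 0 fell of 2 (median log2 change 4.80), of those of interstitial cells of Cajal 1 rose and 1 fell of 3 (-0.89) and of epithelial markers 1 rose and 1 fell of 3 (-0.71). Of immune cell markers 1 rose and 1 fell of 2 (-0.11) and of enteric glia and neuron markers 1 rose and 2 fell of 4 (-0.28), again too few for the list test. Endothelial markers were not called (3 rose and 0 fell of 5; median log2 change 0.78, adjusted p = 0.11, and adjusted p = 0.2 with an estimated correlation). Camera with edgeR called them (median log2 change 0.79, adjusted p = 0.046).

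Lists of p53 and ATF4 responses fell. Of p53 targets 1 rose and 13 fell of 20 (median log2 change -1.34, adjusted p = 2.2e-05, and adjusted p = 0.021 with an estimated correlation), with Btg2 and Zmat3 at log2 -2.23 ± 0.10 and -2.14 ± 0.09. Of serine, one-carbon and ATF4 response genes 2 rose and 18 fell of 25 (median log2 change -0.61, adjusted p = 2.3e-04, and adjusted p = 0.11 with an estimated correlation), with Aldh1l2 at -3.49 ± 0.14. YAP/TAZ targets (5 rose and 14 fell of 21; median log2 change -0.71, adjusted p = 0.019, and adjusted p = 0.14 with an estimated correlation) included a lower Rbms3 (-2.22 ± 0.09) and a higher Ankrd1 (2.87 ± 0.11). Of the growth factors 4 rose and 12 fell of 24 (median log2 change -0.46, adjusted p = 0.027, and adjusted p = 0.23 with an estimated correlation), a call that also ended with that filter: Igf1 and Fgf7 fell (-2.35 ± 0.12 and -1.95 ± 0.09) and Fgf10 rose (2.74 ± 0.21). Interferon-stimulated genes went both ways, 10 up and 10 down of 34 (adjusted p = 0.77), with Rsad2 at 1.76 ± 0.09 and Mx1 at -2.31 ± 0.18. Counts adjusted over the list alone differed from those over all genes in 3 of the 15 called lists: 15 p53 targets fell, 44 ribosomal genes rose, and 16 glycolysis genes rose with 7 falling. With an estimated correlation, 6 lists remained called: mitosis, myofibroblastic markers, noncollagenous matrix, cholesterol synthesis, p53 targets and BMP. Another grouping of the same libraries, which kept most of each group together, also gave 15 called lists.

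**Figure D3:**
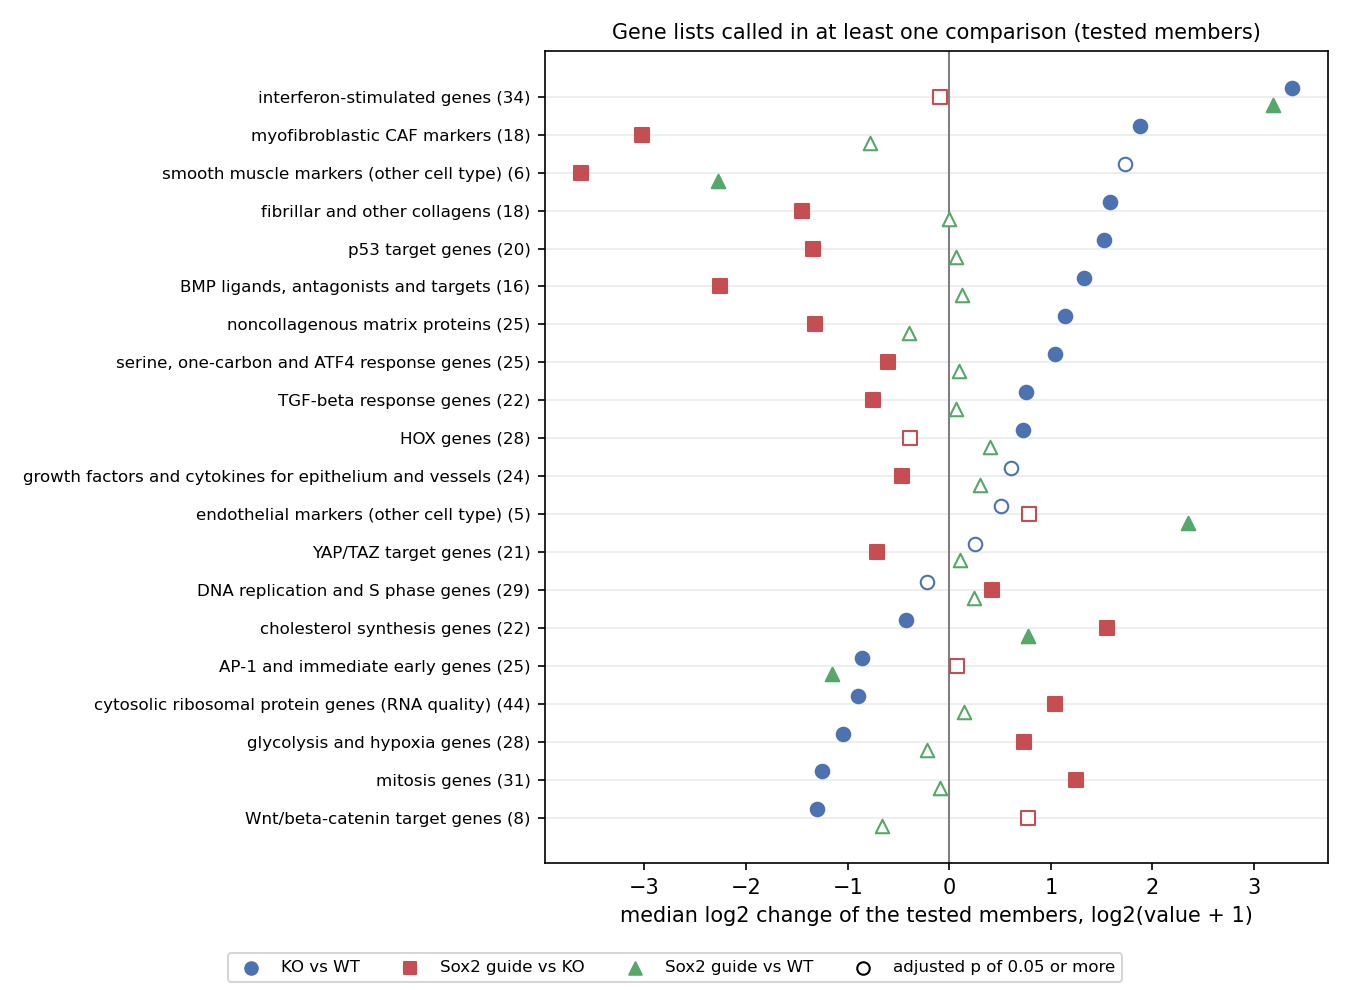
Median log2 change of the tested members of each gene list called in at least 1 comparison, with the number of members in brackets. Circles compare knockout-labelled with WT-labelled, squares Sox2-guide with knockout-labelled and triangles Sox2-guide with WT-labelled libraries; open symbols mark an adjusted p of 0.05 or more.

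The reversal of differences was then counted, as genes called in both comparisons with opposite signs. Sox2, Hoxc8, Nnat (2.399 ± 2.94, 983 ± 85.2 and 2.52 ± 1.79 in the 3 groups), Cadm1 (2.399 ± 2.94, 751 ± 25.1 and 1.42 ± 1.798), an adhesion molecule, and Limch1 were higher in knockout-labelled libraries and lower with the guide. So were St8sia2, Mab21l1 and Entpd3, with 0 reads in WT-labelled libraries and 537 ± 81.9, 286 ± 31.3 and 276 ± 74.96 in knockout-labelled. Pitx1, Nkx2-3, Asb5, Msln, Sprr1a, Pcdh17, Il33 (400.2 ± 56.01, 0.508 ± 1.02 and 143 ± 25.9), a cytokine, and Ptgs2os2 (165 ± 27.5, 0 and 89.6 ± 18.7) went the other way.

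The count was 5395 genes, 63.5% of those called between knockout- and WT-labelled libraries: 2794 of the 4760 higher (58.7%) and 2601 of the 3733 lower (69.7%). Another 501 moved the same way in both comparisons. Both comparisons use the knockout-labelled libraries. In 20 simulated sets of unchanged groups the highest count was 0, and independent lists would share 2574 genes. With no gene changed few are called, so a count near 0 was fixed in advance. Across genes, which are not independent replicates, log2 changes correlated at -0.71, against -0.50 in simulation, with a covariance of -1.64 against -0.034, a difference of -1.61. With the knockout-labelled libraries split 2 and 2 between the comparisons, in all 6 ways, 4288 to 4583 genes reversed where independent lists would share 1901 to 2008. Splitting does not remove a deviation that all knockout-labelled libraries share. Such a deviation also gives opposite signs, so these counts do not tell it from an effect of the Sox2 guide. Without Sox2-guide replicate 1 the count was 5748.

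Of the 5395 genes, 2898 (53.7%) were not called between Sox2-guide and WT-labelled libraries, which were compared to find what differences were left. Amigo2 rose from 22.8 ± 4.89 to 2050.1 ± 221 normalised reads and Tmem176a from 13.9 ± 2.88 to 1465 ± 139. Tmem176b rose from 7.34 ± 5.48 to 1302 ± 206, Slc24a3 from 6.796 ± 4.897 to 689 ± 63.8 and Epb41l4a from 3.35 ± 2.66 to 446 ± 14.8. Bend5, Hoxc13 and Cbx7, a Polycomb protein, had 0 reads in WT-labelled libraries and 255 ± 30.9, 159.95 ± 19.05 and 95.3 ± 33.4 with the guide, at least 103-fold, 65.6-fold and 40.999-fold higher. Thy1, a fibroblast surface protein, fell from 942 ± 88.9 to 0.481 ± 0.961, Igf2r from 1521 ± 263 to 3.63 ± 0.833 and Spock3 from 497 ± 84.7 to 0.937 ± 1.87. Ptgis, prostacyclin synthase (482 ± 23.6), Mab21l2 (303 ± 2.95), Cdh13 (284 ± 15.95) and Trbc2 (236 ± 7.196) had 0 reads with the guide, and Mcpt8 fell from 277 ± 41.6 to 0.556 ± 1.11 (SD over n = 4).

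By limma 6596 genes (52.0%) passed, 3813 higher and 2783 lower in the Sox2-guide libraries, with 1360 and 1052 at least 2-fold and 212 and 219 at least 8-fold. DESeq2 on recovered reads split its 6188 calls into 2958 higher and 3230 lower, 47.8% higher against 57.8% by limma, and median-of-ratios scaling moved the median log2 change by -0.10. The values of 5902 genes (46.6%) did not overlap, against 2.86% by chance. The root mean square log2 difference between these group means was 1.17. Without Sox2-guide replicate 1, 6722 passed. Sox2 did not pass (log2 change -1.08, adjusted p = 0.077; 0 against 2 reads), and without WT replicate 1 or 3 it did (log2 change -1.43 in each).

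Interferon-stimulated genes were higher here too: 33 of 34 rose and 0 fell (median log2 change 3.19, adjusted p = 6.8e-26, and adjusted p = 0.03 with an estimated correlation), Gbp3 to 1701 ± 87.2 and Igtp to 2236 ± 303. Cholesterol synthesis genes (17 rose and 2 fell of 22; median log2 change 0.77, adjusted p = 8.7e-05, and adjusted p = 0.14 with an estimated correlation) included Hmgcs1 (1058 ± 36.7 to 2755 ± 388) and Sqle (963 ± 66.2 to 2387 ± 267). AP-1 and immediate early genes fell (2 rose and 17 fell of 25; median log2 change -1.15, adjusted p = 9.9e-05, and adjusted p = 0.14 with an estimated correlation), with Klf2 and Spry2 at log2 -2.46 ± 0.13 and -2.32 ± 0.12. Of endothelial markers, of another cell type, 4 rose and 0 fell of 5 (median log2 change 2.35, adjusted p = 0.026, and adjusted p = 0.14 with an estimated correlation), Eng from 59.1 ± 14.6 to 386 ± 77.2 and Flt1 from 57.2 ± 19.8 to 284 ± 31.7. Of smooth muscle markers 0 rose and 5 fell of 6 (median log2 change -2.28, adjusted p = 0.026, and adjusted p = 0.14 with an estimated correlation). Lists with too few members to test were epithelial (0 rose and 2 fell of 3, median log2 change -2.95), mesothelial (0 rose and 2 fell of 2, -2.31) and pericyte markers (0 rose and 2 fell of 4, -0.76). So were those of interstitial cells of Cajal (0 rose and 2 fell of 3, -1.99), of immune cells (0 rose and 0 fell of 2, 0.78) and of enteric glia and neurons (2 rose and 1 fell of 4, 0.12). The endothelial call ended with no filter on low values and the smooth muscle call with edgeR. Counts adjusted over the list alone were 34 up for interferon-stimulated genes, 3 up and 17 down for AP-1, 6 down for smooth muscle and 5 up for endothelial markers. They equalled those over all genes for cholesterol synthesis. Only the interferon list remained called with an estimated correlation. Other groupings of the same libraries gave up to 7 called lists, the most where most of each group stayed together. The mitosis list (2 up and 5 down of 31, adjusted p = 0.4), the ribosomal list (16 rose and 5 fell of 44, adjusted p = 0.54) and the myofibroblastic list (5 rose and 7 fell of 18, adjusted p = 0.14) were not called. Camera with edgeR on the recovered reads did call the myofibroblastic list lower (median log2 change -0.85, adjusted p = 0.015).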

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

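All tests of explanations in this part were chosen after the results were seen, except the exact tests of Prkcz, which were set before. Values were looked at again where 1 library of 4 stood far from the rest of its group by Dixon's test, which marked 31 of 419 groups of values against 20.95 expected by chance at 1 in 20, so many are expected from chance alone.

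In Sox2-guide replicate 1, mitochondrial genes took 4.29% of reads (9.39% to 10.3% in the other replicates) and mt-Rnr1 0.375% (2.37% to 2.69%). In the same library mt-Nd2 stood at 23171 normalised reads (79574 to 83504 in the others). The share of Gm42418, a ribosomal RNA-like transcript, was 2.70% in knockout-labelled replicate 1 (3.21% to 3.29% in the others) and 2.27% in Sox2-guide replicate 4 (3.06% to 3.15%). The top 10 genes took 15.8% in knockout-labelled replicate 1 (17.5% to 17.7%). Also apart in Sox2-guide replicate 1, all as the highest value, were Lor at 183, Ly6c1 at 2411, Rpl4 at 16144, Col6a2 at 159.6 and Agrn at 1567 normalised reads.

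In knockout-labelled replicate 4, Sprr1a (9.71), Birc5 (2488) and Actg2 (48.5) were highest and Igsf10 (1712), Acta2 (23742) and Rbms3 (1136) lowest. In replicate 1 of that group Mx1 (874), Ccnd1 (380.1) and Hoxb13 (58.9) were highest, and in its replicate 2 Ldha (1438) was highest and Epb41l4a (353) lowest. Of WT-labelled libraries, replicate 3 was highest for Dcn (1514), Eng (80.8) and Isg15 (533). Of the same group, replicate 4 was highest for Igf1 (131.4) and lowest for Hoxb13 (3.29), and replicate 2 highest for Hand2 (7.22). In the Sox2-guide group, Prkcz was highest (52.5) and Il33 lowest (104.9) in replicate 3, and Cnn1 lowest (4.45) in replicate 2.

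The low mitochondrial share of Sox2-guide replicate 1 lay mostly in ribosomal RNA: mt-Rnr1 and mt-Rnr2 together stood at 0.241 of the mean of the other 3 replicates. Mitochondrial messenger RNA stood at 0.835, which argues against fewer mitochondria or mitochondrial transcripts as the whole cause, though 0.835 is itself below the other replicates (0.966 to 1.04 of their mean). Single genes differed: mt-Nd2, mt-Nd5 and mt-Co1 stood at 0.286, 0.540 and 0.714, each below every other replicate. The abundant mt-Nd1, mt-Nd4 and mt-Cytb stood at 1.06, 0.955 and 1.18. A library of another group under this label was argued against, since its distance to its own group was 0.487 of that to the nearest other group. The bounds for the messenger RNA and for this distance were set after the results were seen. No other cause was tested, and the design gives no biological explanation for a single library.

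Prkcz reads in both groups labelled Prkcz-/- and none in WT-labelled libraries were not put down to chance, since in exact two-sided permutation tests both groups differed from WT-labelled libraries (p = 0.0286 for each, the smallest the test can give; adjusted p = 0.0312 over 12 tests). A shift of the whole region was argued against, since the 36 tested genes within 1 Mb had median log2 changes of 0.25 and 0.35 against WT-labelled libraries, with median absolute deviations of 0.99 and 0.69, far below the change of Prkcz. Single genes there changed strongly in either direction, AW011738 by 5.67 and 4.59 and Pusl1 by -6.87 and -5.26. For the 32 reads in the knockout-labelled libraries, an exchange of the WT and knockout labels cannot be told apart from a transcript left by the deleted allele, since the deleted part is not given in the sources used here. An exchange of those labels alone would leave the 54 reads of the Sox2-guide libraries unexplained. A transcript left by the deleted allele does not by itself explain the 0 reads of the WT-labelled libraries.

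Hoxc and other transcription factor genes were on in one group and near 0 in another. A lower depth of the group near 0 was argued against as the cause: over all pairs of groups, the shallowest library of one held at least 0.532 of the reads of the deepest of the other. Different proportions of the same cells cannot be told apart from other explanations: genes lost in knockout-labelled libraries kept a median of 0.178% of their WT level, but they were picked for being near 0, so the test is void. Groups grown from cells of different origin or clone stay possible. Between Sox2-guide and WT-labelled libraries 13 genes were on or off, against 51 between knockout- and WT-labelled ones. Between Sox2-guide and knockout-labelled libraries, which share the Prkcz-/- label, 33 were. The labels do not say whether the groups share a source of cells, so origin and group cannot be told apart. Loss of Prkcz and the Sox2 guide, which the design names, stay open as well and were not tested separately.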

How the results depend on the processing

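The scaling without mitochondrial genes and Gm42418 was chosen after the results were seen, and the split of the knockout-labelled libraries was set before the data were examined. No named result changed direction past its threshold. Leaving out each library in turn gave 8066 to 8200 genes for knockout- against WT-labelled libraries, 7103 to 7816 for the Sox2 guide against knockout and 5991 to 6722 for the Sox2 guide against WT, 4983 to 5748 reversed genes, and 15, 15 and 5 called lists. For Sox2 between the Sox2-guide and WT-labelled libraries the log2 change ran from -1.43 to -0.70, passing without WT replicate 1 or 3 (adjusted p = 0.020 in each; 0.020 to 0.27 over the alternatives), since those libraries held 0 of the 2 reads. Across the other settings the counts were 6583 to 9469, 5637 to 8394 and 4473 to 6982, the lowest from the 1.5-fold threshold and the highest from dropping the filter or from array weights. Genes called in the opposite direction numbered 0, except 1 between the Sox2 guide and knockout with quantile scaling. That scaling also called Prkcz there (log2 change 1.26, adjusted p = 0.026; 0.026 to 0.44 over the alternatives); the cause was not tested. The filter at 50 normalised reads left 3 lists called between the Sox2 guide and WT, with fewer genes tested, and tested no Prkcz. An estimated correlation left 1, 6 and 1 lists; the cause was not tested. Over the named genes other than Prkcz, Sox2, Sfrp1 and Sfrp2, leaving out a library ended 37 calls and made 3, and other settings ended 31 and made 5. For lists, the other settings ended 33 and made 10, and no called list changed the sign of its median under another scaling or count tool. Replicate numbers did not pair the samples, by correlations across groups after the group means were removed. Those of same-numbered libraries were -0.04 to 0.13, 1 of 12 was over 0.1, and 4 of 12 libraries correlated best with their own number. The replicate block gave 8508, 7693 and 6627 genes. Depth limits low genes most, since 3 reads are worth up to 11.2 units.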

Other observations

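In this part, the thresholds for genes on or off and the choice of genes near Prkcz, of transcription factor genes and of chromosomes were made after the data were seen, and the regroupings were laid down before the data were examined.

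Of single transcription factor genes outside the HOX list, Foxp2 stood at 535 ± 41.8, 10.3 ± 1.602 and 435 ± 44.5 normalised reads in the WT-labelled, knockout-labelled and Sox2-guide groups (SD, n = 4), Gata6 at 354 ± 50.8, 4.199 ± 3.003 and 132 ± 29.1, and Satb1 at 83.4 ± 16.04, 3.57 ± 3.37 and 281 ± 32.7. The reverse order held for Hand2 (4.19 ± 2.03, 650.2 ± 43.7 and 1.04 ± 1.204) and Tbx18 (252 ± 28.8, 1389 ± 113 and 179 ± 35.8), while Pax3 stayed high with the guide (32.5 ± 8.35, 1579 ± 185 and 627 ± 105). Counting genes with a mean of 200 normalised reads or more in one group and with at most 3 reads in the other, 33 were gained and 18 lost in knockout-labelled libraries. Of these, 15 were off again and 3 on again in the Sox2-guide libraries.

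Of the markers of intestinal fibroblast subsets 8 rose and 4 fell of 14 between knockout- and WT-labelled libraries, and the list was not called (median log2 change 1.04, adjusted p = 0.55, and adjusted p = 0.65 with an estimated correlation). Pdgfra stood at 249 ± 32.6, 1448 ± 281 and 40.9 ± 5.94, Ly6a, also called Sca-1, at 890.2 ± 70.9, 114 ± 32.3 and 6976 ± 1050.05, and Cd34 at 4599 ± 208, 767 ± 92.8 and 2669.6 ± 275. Of the 3 tested epithelial markers, Krt7 stood at 6.65 ± 3.12, 36.7 ± 7.003 and 6.19 ± 6.52, Krt19 at 102 ± 28.1, 4.601 ± 4.05 and 12.5 ± 4.91, and Krt18 at 33.3 ± 6.04, 1.56 ± 3.13 and 0. Of the 2 tested immune cell markers, Csf1r stood at 3.27 ± 2.66, 34.3 ± 10.4 and 7.04 ± 3.89, and Cd68 at 25.4 ± 5.02, 9.54 ± 6.0995 and 35.9 ± 10.6. Among Wnt ligands and enhancers, Wnt5a stood at 566 ± 47.7, 877 ± 73.2 and 640.1 ± 18.6, Wnt7b at 277 ± 31.7, 1.29 ± 1.56 and 23.6 ± 1.44, and Rspo3 at 46.05 ± 19.6, 19.6 ± 7.41 and 0.937 ± 1.87. Of that list's 7 tested genes 1 rose and 6 fell between the Sox2 guide and knockout (median log2 change -3.24, camera adjusted p = 0.081). It was called there with no filter (camera adjusted p = 0.019), with only the libraries compared (0.031) and with edgeR (0.0043). Against WT, 4 rose and 1 fell in knockout-labelled libraries (adjusted p = 0.59), and 1 rose and 3 fell with the guide (0.40).

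Near Prkcz on chromosome 4, Pusl1 fell in both groups labelled Prkcz-/- (174 ± 6.92, 1.02 ± 2.03 and 3.63 ± 0.833). AW011738 rose in both (means 3.995, 143.7 and 67.4), as did Fndc10 (5.06, 111.9 and 18.3). Isg15, an interferon-stimulated gene, stood at 456 ± 51.7, 4815 ± 795 and 6509.6 ± 1349, and Agrn, its neighbour, at 166 ± 33.8, 1356 ± 104 and 1093 ± 319. Medians of log2 change over whole chromosomes were not all near 0. Chromosome 1 stood at 0.55 between knockout- and WT-labelled libraries and -0.53 between the Sox2 guide and knockout, where chromosome X stood at 0.59. Chromosomes 19, 15 and 9 stood at 0.55, 0.52 and -0.45 between the Sox2 guide and WT. They were shifted between knockout- and WT-labelled libraries too (0.39, 0.45 and -0.32), so these shifts were not particular to the guide. In that comparison chromosomes 7 and 3 stood at 0.42 and 0.40, and chromosomes 14 and 8 at -0.42 and -0.35. The cause was not tested. Medians over all tested genes were 0.12, -0.013 and 0.076.

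The libraries were placed in 35 groupings for each pair of groups and 100 for the reversal, the real one included in each. The others mixed libraries of groups that lay apart, which widens the spread within groups and keeps counts of genes low. Low counts there were thus set in advance. They do not exclude differences between cultures that the libraries of a group may share. Only 1 grouping, the real one, gave as many, with 8493, 7689 and 6596 genes called against at most 0, 0 and 1 in the others, and 5395 reversed genes against at most 0. For the 15 lists called between knockout- and WT-labelled libraries only the real grouping gave as many. This argues against chance placing of the libraries, but by a margin of 1 list (highest other 14). With an estimated correlation 1 list remained called. In each comparison, the other groupings with the most lists kept most libraries of each group together, and thus part of the real difference. Groupings that mixed the 2 groups evenly gave 0 to 2 lists. For the 15 lists of the Sox2 guide against knockout, 2 of the 35 groupings gave as many (highest other 15). For the 5 lists of the Sox2 guide against WT, 6 of the 35 did (highest other 7). Since the other groupings among these keep part of the real difference, neither count shows or excludes chance.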
